A study of Homo sapiens with 29 samples.

How the data were processed

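The samples were BEAS-2B cultures treated for 24 h with N-OH-PhIP at 9 doses or with DMSO at 1%, 29 arrays in 10 groups. Per the labels' protocols, cells stood at about 70% confluence in serum-free LHC-9 medium, RNA was isolated with an All-Prep kit, and 40 ng was amplified with NuGEN Ovation, biotin-labelled and hybridised to an Affymetrix 3′ expression array. Per the submitters' processing notes, signals came from GCOS, whose version is not given in the sources used here. The deposited values are linear intensities per probe set, normalized by the authors with a method that is not given in the sources used here. Means after trimming 2% from each end ran from 299 to 309 over the arrays, a spread of 3.18%, within the 5% set for leaving the values without further normalization. Detection calls were not used here, so levels under the minimum given below were not shown to be above background in a group, and log2 changes from or to such levels, and their order, depend on the offset. No 2 arrays had identical values, array medians ran from 35.8 to 38.4, and over tested probe sets the medians spread by 0.0946 log2. Principal components 1 and 2 held 58.8% and 10.1% of the variance.

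Of 54675 probe sets, 62 were controls, 41091 had 1 gene symbol, 1801 had several and 11721 had none. Symbols came from the array's annotation table, and 41043 of the probe sets with 1 symbol were matched to the RefSeq gene table by gene identifier, which changed 0 symbols. Control probe sets were left out of these tests and compared in a fit of their own, from which some are not reported here. Values were log2(intensity + 16), an offset that shrinks changes of dim probe sets. Probe sets with a mean log2 value at or above the median of 5.74, an intensity of 37.4, were tested, 27307 in all for 12174 genes.

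Groups, comparisons, alternatives and gene lists were fixed before the data were examined. Each dose was compared with DMSO in a single limma fit with a mean for each of the 10 groups, empirical Bayes moderation with a mean-variance trend, 19 residual degrees of freedom and two-sided tests. P values were adjusted with Benjamini-Hochberg over the 27307 probe sets of a comparison at a threshold of 0.05. The dose trend was a limma slope on log10 dose over the 26 treated arrays, given per 10-fold dose. The mean of the 9 doses against DMSO and a moderated F test over the 10 groups came from the fit of the single doses. All comparisons with DMSO share its 3 arrays, so their errors are not independent. Because the values were normalized to a common level, the balance of higher and lower probe sets is relative to that level. With R 4.3.3 and limma 3.58.1 the tests were run, and figures were drawn with matplotlib 3.10.9.

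Of 33 gene lists fixed before the data were examined, the 29 with at least 5 measured genes were tested with camera, which compares a list with the other genes, at a preset correlation of 0.01. Each gene was represented by its tested probe set of highest mean, and p was adjusted over the lists of a comparison. A list is called at adjusted p 0.05. List counts of genes that rose or fell used the calls over all probe sets, and counts adjusted over the list alone used only its members. The lists name 17 symbols that matched no single gene of the RefSeq gene table by symbol or synonym, 12 of them of the mitochondrial genome. These were left out, without a check of whether the array measures them.

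Genes were named by a fixed rule. For 1000 nM, the trend and the mean of doses these were the 10 higher and 10 lower genes of largest change among called probe sets with 1 symbol, 1 probe set per gene, and for other doses 3 and 3. At single doses each array of the dose had to lie on the same side of every DMSO array. From each called list up to 4 members past the threshold were named, or the 2 with the smallest p where none passed. CDKN1A, MDM2, GDF15, CYP1A1, CYP1B1, NQO1 and HMOX1 were always named.

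Alternatives set beforehand were an offset of 1, quantile normalization, median centring, no level filter, the upper 25% of mean level, no mean-variance trend, a replicate block, array weights, a covariate of the 3′ to 5′ log2 ratio of actin and GAPDH, only the dose and DMSO in the fit, and a minimum change of 1.5-fold. For the trend, DMSO was also set 10-fold below the lowest dose, or the slope was linear in dose. For lists, camera with an estimated correlation, fry, which tests the list alone, and the mean of all probe sets of a gene were tried. Each array was left out in turn. Chosen after seeing the data were the fit without 5 nM replicate 3 and 500 nM replicate 3, the shifts of the p53 and immediate early lists under each alternative, and a reference of the 0.1 and 1 nM arrays. Estimation of array weights ended with a convergence warning and gave 500 nM replicate 1 a weight of 1.84e-05, so all counts with array weights rest on estimates that did not converge.

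The code was tested on simulated data with 27307 probe sets and independent noise. Of probe sets changed 1.25-, 1.5-, 2- and 4-fold, 32%, 88%, 98% and 100% were called, the recovered change was 1.01 of the true one, and 7 unchanged probe sets were called, 4.22% of the calls. Slopes of 0.1 and 0.3 were called in 83% and 100%. With no change anywhere 1 probe set was called at any dose, and 0 of 29 lists were called. With the p53 list raised by 0.2, that list alone was called, with a recovered median of 0.178. Because the simulated noise was independent between probe sets, these list results do not show how often lists of correlated genes are called without a change.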

Results

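RNA was measured in BEAS-2B cells, a human bronchial epithelial line immortalised with an adenovirus-SV40 hybrid virus, after 24 h in serum-free medium with N-OH-PhIP or with its solvent DMSO at 1%. N-OH-PhIP is the N-hydroxylated metabolite of PhIP, a heterocyclic amine of cooked meat and tobacco smoke that forms DNA adducts once activated. Per the labels, the series asks at which dose a transcriptional effect appears. The 29 arrays fell into 10 groups: DMSO and 0.1, 0.5, 1, 5, 10, 50, 100, 500 and 1000 nM. Each group held 3 arrays, from triplicate cultures per the labels, except 0.5 nM, which held 2 (replicates 1 and 3). The labels' design text puts the lowest dose at 0.5 nM while sample titles reach 0.1 nM, and the titles were used. Normalized intensities ran from 4.26 to 20095, and arrays of a group correlated at 0.980 to 0.998 across tested probe sets. The number of arrays limits the precision. In all, 27307 probe sets representing 12174 genes were tested. All 9 doses were compared with the same 3 DMSO arrays, so a chance deviation of those arrays enters every comparison. Intensities below are group means ± SD (n = 3, and n = 2 at 0.5 nM), and log2 changes are against DMSO with their SE. The largest changes named are those of probe sets with a single gene symbol.

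Expression of p53 target genes moved with dose over the upper part of the range. Of the 29 measured, 11 rose at 50 nM, 21 at 100 nM, 28 at 500 nM and 27 at 1000 nM, and 0 fell at these 4 doses. Their median log2 change was 0.15 at 10 nM, 0.25 at 50 nM, 0.41 at 100 nM, 0.87 at 500 nM and 0.64 at 1000 nM. Over all genes, 16345 of the 27307 probe sets (59.9%) changed at 1000 nM, 12392 at 500 nM, 792 at 100 nM and 72 at 50 nM. At lower doses 66 changed at 10 nM, 302 at 5 nM, 213 at 1 nM, 12 at 0.5 nM and 163 at 0.1 nM. The counts of at least 1.5-fold were 6456, 3436, 192, 24, 19, 59, 47, 4 and 51 from 1000 down to 0.1 nM. Probe sets at an unadjusted p under 0.05 (limma) numbered from 2415 at 50 nM to 17266 at 1000 nM. With no change 1365 are expected on average, but because probe sets are correlated a single count can stray far from that. The log2 ratio of 3′ to 5′ control probe sets, a measure of RNA and amplification quality, also moved with dose in its mean over actin and GAPDH. It was 1.18 ± 0.04 (SD) in DMSO, 1.23 ± 0.05 at 0.1 nM, 1.2504 ± 0.08 at 0.5 nM, 1.35 ± 0.06 at 1 nM and 1.254 ± 0.06 at 5 nM. At higher doses it was 1.16 ± 0.05 at 10 nM, 1.16 ± 0.04 at 50 nM, 1.16 ± 0.06 at 100 nM, 0.93 ± 0.08 at 500 nM and 0.84 ± 0.02 at 1000 nM. The fall was that of actin alone, at 2.21 in DMSO, 1.67 at 500 nM and 1.52 at 1000 nM. The GAPDH ratio did not fall, at 0.14, 0.20 and 0.17.

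**Figure D1:**
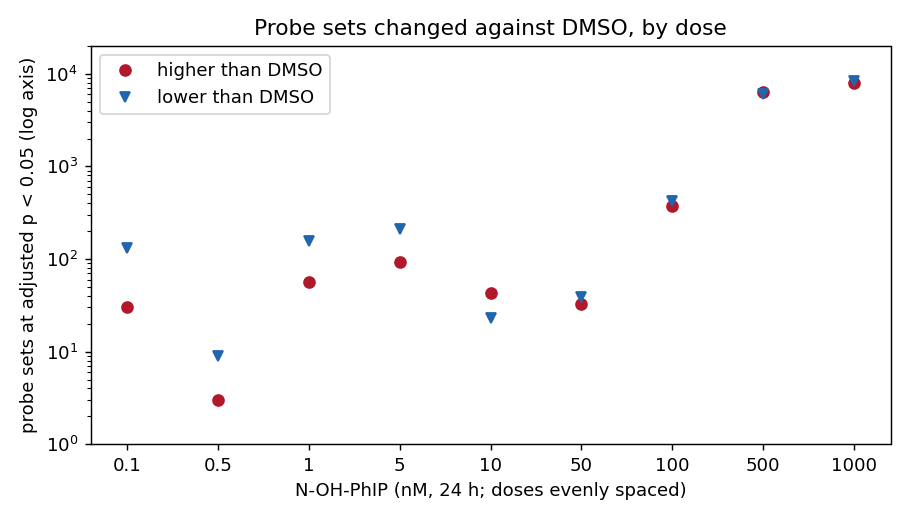
Probe sets changed against DMSO at adjusted p 0.05 by dose of N-OH-PhIP (log axis of counts; circles higher, triangles lower). At 1000 nM 7892 were higher and 8453 lower, against 33 and 39 at 50 nM.

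**Figure D2:**
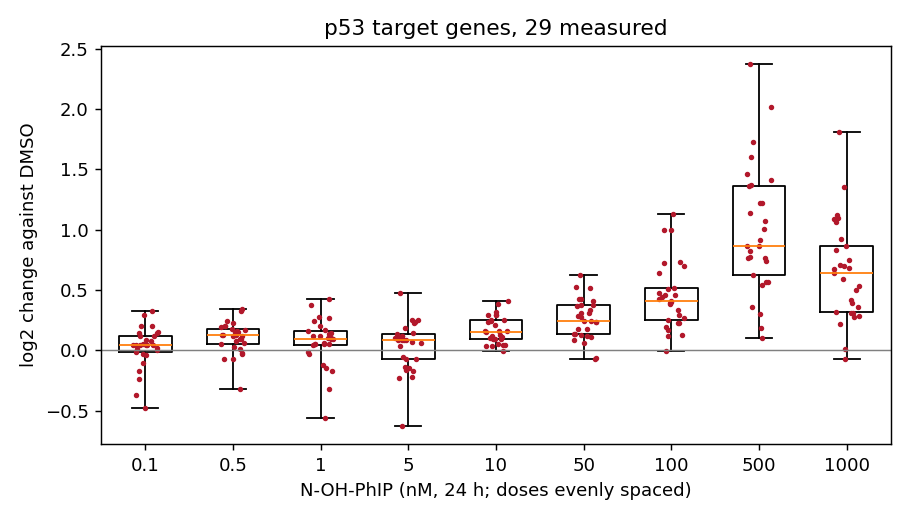
Log2 change against DMSO of the 29 measured p53 target genes at each dose (points, genes; boxes, quartiles; whiskers, range). The median was 0.04 at 0.1 nM, 0.87 at 500 nM and 0.64 at 1000 nM.

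At 1000 nM, ID2, an inhibitor of basic helix-loop-helix factors, rose from 25.3 ± 4.26, a level not shown to be above background, to 595 ± 37.3. Its log2 change was 3.89 ± 0.12 with the offset. IL11, a cytokine of the IL-6 family, rose from 53.7 ± 14.8 to 609 ± 50.8 (3.18 ± 0.12). SGK1, a serum- and glucocorticoid-induced kinase, rose from 236 ± 18.6 to 2186 ± 74.7 (3.13 ± 0.13). NBEA, a large protein of vesicle trafficking, fell from 652 ± 8.43 to 60.7 ± 15.7 (-3.14 ± 0.12). LINGO2 fell from 219 ± 7.35 to 16.3 ± 0.615, a level not shown to be above background (-2.86 ± 0.12 with the offset). The other large increases were SHISA2 at 3.31 ± 0.12, PCDH10, a protocadherin, at 3.33 ± 0.14, SP6, a zinc finger factor, at 3.14 ± 0.11 and MARCKSL1 at 3.02 ± 0.13. JMJD6 (3.45 ± 0.15) and SLC25A3, the mitochondrial phosphate carrier (3.10 ± 0.10), rose in every tested probe set, 3 and 2. CLDND1 rose by 3.53 ± 0.17 in 1 probe set, while its other 2 tested probe sets did not pass the test. Among the decreases were PARD3, a polarity protein (-2.90 ± 0.11), LTBP1, which binds latent TGF-β (-2.87 ± 0.15), GLIS3 (-2.66 ± 0.09) and FOXP2 (-2.53 ± 0.09), both transcription factors. RIMS2 (-2.68 ± 0.13), SYT1, a synaptotagmin (-2.60 ± 0.12), SAMD12 (-2.63 ± 0.11) and IMMP2L, a mitochondrial inner membrane peptidase (-2.50 ± 0.13), also fell. Adjusted p for these 20 genes ran from 2.6e-18 for ID2 to 1.4e-14 for LTBP1 (limma).

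At 1000 nM, 27 of the 29 p53 target genes rose and 0 fell, and the same counts held adjusted over the list alone. The list was called with a camera adjusted p of 3.9e-11 and with adjusted p = 0.023 with an estimated correlation. ACER2, an alkaline ceramidase, rose by 1.81 ± 0.11, SESN1, a sestrin, by 1.35 ± 0.09, TP53I3, a quinone oxidoreductase, by 1.12 ± 0.08 and PLK2, a polo-like kinase, by 1.10 ± 0.13. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 4663 ± 230 to 6740 ± 119 (0.53 ± 0.05). MDM2, the ubiquitin ligase of p53, rose by 0.28 ± 0.05 and GDF15, a secreted stress cytokine, by 0.68 ± 0.07. Hypoxia and glycolysis genes rose in 16 of 20 members and fell in 2 (16 and 2 adjusted over the list alone; median 0.71, adjusted p 1.9e-07, and adjusted p = 0.023 with an estimated correlation). ALDOC, an aldolase, rose from 315 ± 7.35 to 1625 ± 109 (2.31 ± 0.10). ADM, the vasodilator adrenomedullin, rose by 1.62 ± 0.08, NDRG1 by 1.55 ± 0.09 and ANKRD37 from 324 ± 37.8 to 788 ± 64.1. Cholesterol synthesis genes rose in 15 of 17 and fell in 0 (15 and 0 adjusted over the list alone; median 0.54, adjusted p 2e-07, and adjusted p = 0.039 with an estimated correlation). DHCR7, the last reductase of the pathway, rose by 1.18 ± 0.10, IDI1, an isomerase of isoprenoid units, by 1.14 ± 0.08 and SC5D, a sterol desaturase, by 1.07 ± 0.11. INSIG1, a regulator of the sterol sensor, rose by 1.15 ± 0.11.

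The other 6 lists called at 1000 nM lost their call with an estimated correlation. Replication-dependent histone genes rose in 5 of 7 and fell in 0 (5 and 0 adjusted over the list alone; median 1.11, adjusted p 0.002, and adjusted p = 0.17 with an estimated correlation). H2BC5 rose by 1.73 ± 0.11, H2BC12 by 1.71 ± 0.09, H2BC21 by 1.14 ± 0.14 and H2AC8 by 1.11 ± 0.14, and the 5′ controls of 18S and 28S ribosomal RNA were higher at this dose too. TGF-beta and SMAD targets rose in 15 of 20 and fell in 1 (16 and 1 adjusted over the list alone; median 0.57, adjusted p 3.4e-05, and adjusted p = 0.083 with an estimated correlation). Besides ID2, BAMBI, a decoy receptor of the pathway, rose by 2.83 ± 0.16, ANGPTL4 by 1.52 ± 0.15 and SMAD7, an inhibitory SMAD, by 1.19 ± 0.12. Immediate early genes, which respond within minutes to growth signals, rose in 16 of 23 and fell in 2 (16 and 2 adjusted over the list alone; median 0.40, adjusted p 0.00098, and adjusted p = 0.47 with an estimated correlation). FOSB rose by 2.42 ± 0.17, FOSL1 by 1.63 ± 0.19, EGR3 by 1.28 ± 0.19 and NR4A1 by 1.11 ± 0.12. Heat shock genes rose in 11 of 15 and fell in 1 (11 and 1 adjusted over the list alone; median 0.43, adjusted p 0.00057, and adjusted p = 0.14 with an estimated correlation). BAG3, a co-chaperone, rose by 1.27 ± 0.08, DNAJA1 by 0.75 ± 0.05, HSPH1 by 0.61 ± 0.07 and STIP1 by 0.59 ± 0.07. NRF2 antioxidant genes rose in 15 of 23 and fell in 4 (15 and 5 adjusted over the list alone; median 0.29, adjusted p 0.023, and adjusted p = 0.32 with an estimated correlation). AKR1C3, an aldo-keto reductase, rose by 0.96 ± 0.10, SRXN1, a sulfiredoxin, by 0.86 ± 0.07, NQO1 by 0.32 ± 0.04 and HMOX1, heme oxygenase, by 0.80 ± 0.14. ME1, malic enzyme (-0.89 ± 0.07), and SLC7A11, the cystine transporter (-0.86 ± 0.06), fell. Inflammatory cytokines and NF-kB targets rose in 9 of 19 and fell in 2 (9 and 2 adjusted over the list alone; median 0.26, adjusted p 0.035, and adjusted p = 0.48 with an estimated correlation). PTGS2, the inducible cyclooxygenase, rose by 1.13 ± 0.20, LIF by 1.12 ± 0.12, the chemokine CXCL8 by 1.07 ± 0.22 and IL1B by 0.84 ± 0.12.

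The other 20 lists tested at 1000 nM were not called, and each is given by its median log2 change, its members that rose and fell, and its camera adjusted p. Repair and checkpoint lists were nucleotide excision repair (-0.05; 8 rose and 7 fell of 23; 0.98), Fanconi and homologous recombination repair (-0.29; 3 and 14 of 22; 0.052), base excision and mismatch repair (-0.30; 3 and 11 of 18; 0.096) and translesion synthesis and checkpoint signalling (-0.14; 4 and 13 of 25; 0.33). The excision repair list had a mean of -0.04 while its test pointed up. Growth lists were DNA replication and G1/S genes (0.06; 15 and 7 of 35; 0.11), G2/M and mitosis genes (-0.11; 8 and 17 of 35; 0.27), apoptosis genes (0.08; 7 and 8 of 23; 0.36), mitochondrial respiratory chain genes (0.12; 11 and 5 of 27; 0.052) and cytosolic ribosomal proteins (0.01; 5 and 0 of 26; 0.18). Xenobiotic lists were aryl hydrocarbon receptor target genes (0.15; 4 and 2 of 9; 0.24) and enzymes and transporters of heterocyclic amine metabolism (0.12; 6 and 2 of 11; 0.063). Stress lists were the unfolded protein and integrated stress response (-0.12; 3 and 12 of 26; 0.096), metallothioneins (0.07; 1 and 1 of 8; 0.6) and interferon-stimulated genes (0.13; 10 and 4 of 21; 0.1). Lineage lists were epithelial keratin and adhesion genes (0.09; 14 and 7 of 30; 0.052), squamous differentiation genes (0.04; 2 and 0 of 7; 0.45), mesenchymal and extracellular matrix genes (0.24; 9 and 3 of 15; 0.052) and markers of differentiated airway cells (0.09; 2 and 0 of 6; 0.45). Hormone lists were estrogen response genes (0.20; 4 and 2 of 10; 0.26) and retinoid response genes (0.43; 4 and 1 of 5; 0.096). Adjusted over the list alone, these 20 lists had the same counts as over all genes except aryl hydrocarbon receptor target genes (5 rose), apoptosis genes (8 and 8), airway markers (0 rose), respiratory chain genes (13 rose), ribosomal proteins (4 rose) and estrogen response genes (5 rose). CYP1B1, a cytochrome of the receptor's battery, fell by 0.30 ± 0.11 at 1000 nM. CYP1A1, its best known target, lay under the level minimum, at 28.0 ± 6.68 in DMSO and 12.4 ± 1.64 at 1000 nM, and was not tested.

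Markers of other cell types were largely under the level minimum, with 3 of 20 leukocyte, 3 of 16 endothelial and 3 of 16 fibroblast markers above it, too few for the list test. Of the leukocyte markers, CD74 (0.51 ± 0.09), CORO1A (0.35 ± 0.12) and CD14 (0.78 ± 0.12) rose at 1000 nM. Of the fibroblast markers, COL1A1 rose by 0.39 ± 0.10, and 0 of the endothelial markers ENG, FLT1 and EGFL7 were called. Among airway markers AGR2 (0.23) and CIMAP3 (0.28) rose. Of the polyadenylated RNA of the mitochondrial genome, 1 of 13 symbols was matched and 0 genes passed the level minimum. At 1000 nM, 7892 probe sets rose and 8453 fell. Among the 5102 genes that had several tested probe sets and at least 1 call, 650 (12.7%) had calls in both directions, so a single probe set does not always speak for its gene.

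**Figure D3:**
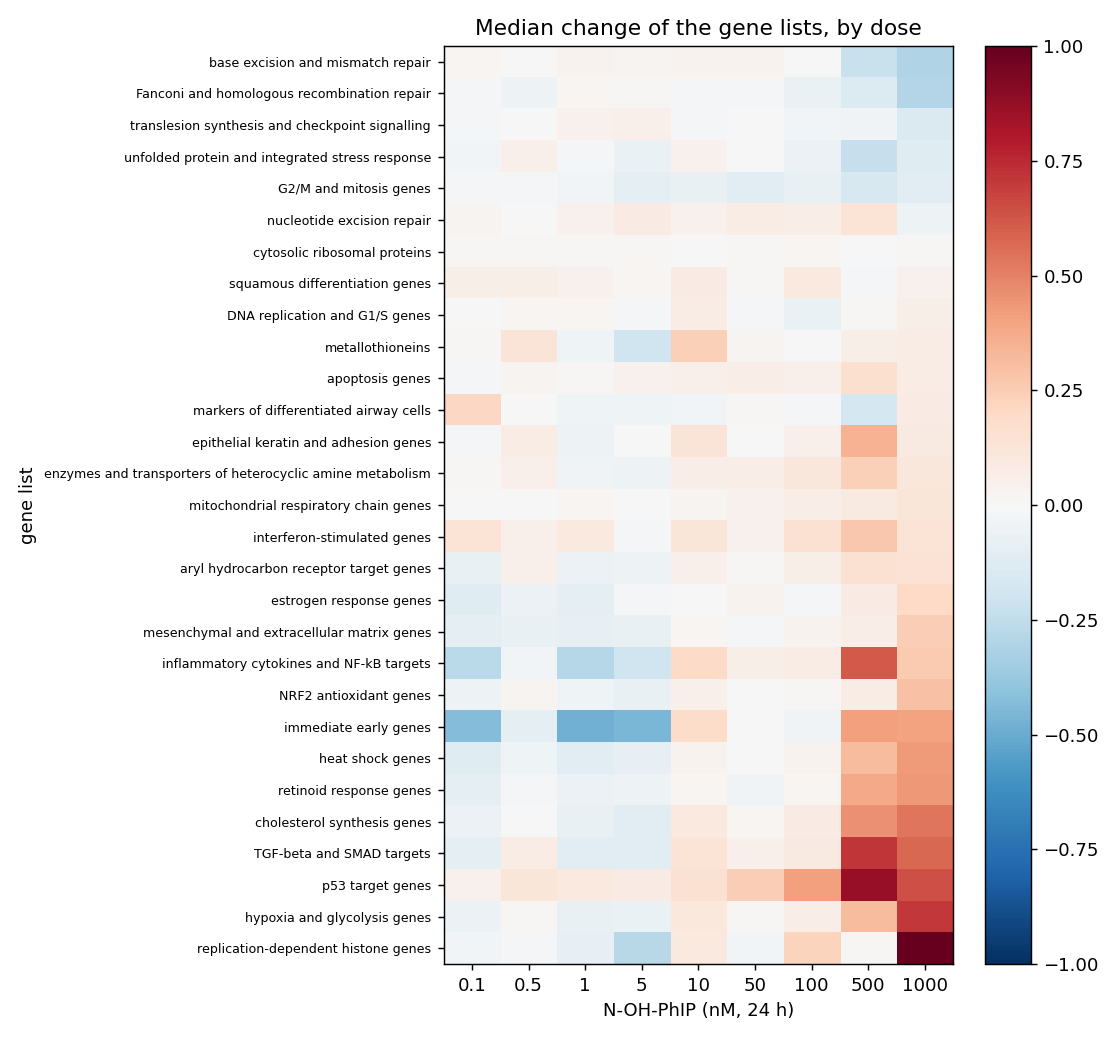
Median log2 change against DMSO of the 29 tested gene lists (lists in order of their value at 1000 nM) at each dose, with colours limited at -1 and 1. Replication-dependent histone genes stood at 1.11 at 1000 nM and p53 target genes at 0.64.

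At 500 nM, inflammatory genes and p53 target genes rose together. IL6, a cytokine of acute inflammation, rose from 97.6 ± 13.5 to 708 ± 213 (2.64 ± 0.18), LIF, of the same family, rose by 1.85 ± 0.12, CXCL8 by 1.56 ± 0.22 and IL1B by 1.39 ± 0.12. In that list 13 of 19 rose and 0 fell (14 and 1 adjusted over the list alone; median 0.61, adjusted p 7.3e-05, and adjusted p = 0.31 with an estimated correlation). The p53 list rose in 28 of 29 (28 adjusted over the list alone; adjusted p 2.4e-21, and adjusted p = 0.0018 with an estimated correlation), with ACER2 at 2.37 ± 0.11, TP53I3 at 2.01 ± 0.08, SESN1 at 1.73 ± 0.09 and the death receptor FAS at 1.61 ± 0.05. CDKN1A rose by 0.77 ± 0.05, MDM2 by 0.54 ± 0.05 and GDF15 by 0.92 ± 0.07. The largest increases were OTP, a homeobox factor (2.92 ± 0.14), RASAL1, a Ras GTPase activator (2.87 ± 0.14), and SP6 (2.87 ± 0.11). The largest decreases were IMMP2L (-3.17 ± 0.13), DPYD, which degrades pyrimidines (-2.94 ± 0.12), and DIAPH2, a formin (-2.84 ± 0.12).

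Other lists called up at 500 nM lost the call with an estimated correlation. Epithelial keratin and adhesion genes rose in 17 of 30 and fell in 3 (19 and 3 adjusted over the list alone; median 0.35, adjusted p 6.9e-05, and adjusted p = 0.13 with an estimated correlation), led by KRT15 at 1.66 ± 0.16, KRT8 at 1.45 ± 0.14, KRT80 at 1.20 ± 0.11 and SFN, stratifin, at 1.16 ± 0.08. TGF-beta and SMAD targets rose in 14 of 20 (14 adjusted over the list alone; median 0.71, adjusted p 2.9e-05, and adjusted p = 0.093 with an estimated correlation), with ID2 at 2.00 ± 0.12, TGFB2 at 1.47 ± 0.14, ANGPTL4 at 1.31 ± 0.15 and INHBA at 1.29 ± 0.17. Interferon-stimulated genes rose in 12 of 21 (12 adjusted over the list alone; median 0.27, adjusted p 0.0017, and adjusted p = 0.4 with an estimated correlation), among them ISG15, a ubiquitin-like modifier (1.96 ± 0.12), IFIT3 (from 169 ± 24.1 to 507), TAP1, a peptide transporter (1.13 ± 0.09), and OASL (0.94 ± 0.13). Heat shock genes rose in 11 of 15 (11 adjusted over the list alone; median 0.32, adjusted p 9.9e-05, and adjusted p = 0.093 with an estimated correlation), including HSPA4L (1.12 ± 0.08), BAG3 (0.94 ± 0.08), HSPB1 (0.58 ± 0.09) and DNAJB1 (0.53 ± 0.08). Cholesterol synthesis genes rose in 15 of 17 (16 adjusted over the list alone; median 0.45, adjusted p 9.2e-06, and adjusted p = 0.093 with an estimated correlation), among them HSD17B7 (0.87 ± 0.06), NSDHL (0.72 ± 0.06), INSIG1 (0.69 ± 0.11) and IDI1 (0.64 ± 0.08). Hypoxia and glycolysis genes rose in 13 of 20 and fell in 1 (13 and 1 adjusted over the list alone; median 0.32, adjusted p 0.00072, and adjusted p = 0.11 with an estimated correlation), with ADM at 1.45 ± 0.08, ALDOC at 1.28 ± 0.10, PFKFB4 at 1.20 ± 0.13 and ENO2 at 0.60 ± 0.09.

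Immediate early genes rose in 13 of 23 at 500 nM and fell in 1 (13 and 1 adjusted over the list alone; median 0.41, adjusted p 0.0034, and adjusted p = 0.49 with an estimated correlation). FOSL1 rose by 1.86 ± 0.19, NR4A1 by 1.20 ± 0.12, FOSB by 1.02 ± 0.17 and the phosphatase DUSP1 by 0.97 ± 0.12. Without 500 nM replicate 3 that list had a median of 0.23 and was no longer called (adjusted p 0.064). Of the 11 lists called at 500 nM, 2 went down. Unfolded protein and integrated stress response genes fell in 18 of 26 and rose in 1 (19 and 1 adjusted over the list alone; median -0.23, adjusted p 1.6e-05, and adjusted p = 0.093 with an estimated correlation), with TRIB3 at -1.01 ± 0.07, HERPUD1 at -0.85 ± 0.05 and CHAC1 at -0.77 ± 0.12, while ATF3 rose by 0.77 ± 0.09. G2/M and mitosis genes fell in 16 of 35 and rose in 6 (17 and 7 adjusted over the list alone; median -0.16, adjusted p 0.017, and adjusted p = 0.48 with an estimated correlation). CDCA3 (-0.80 ± 0.06) and AURKA, a mitotic kinase (-0.48 ± 0.04), fell, while KIF20A (0.48 ± 0.09) and DLGAP5 (0.45 ± 0.07) rose. NQO1 (0.39 ± 0.04) and HMOX1 (0.89 ± 0.14) rose and CYP1B1 fell by 0.47 ± 0.11 without a call of their lists. Of other cell markers, CD74 (0.52), CORO1A (0.64), COL1A1 (0.74) and CIMAP3 (0.49) rose, and FBLN1 (-0.65), AGR2 (-0.24), SFTPC (-0.33) and SFTPB (-0.55) fell. At 500 nM, 6304 probe sets rose and 6088 fell, and 253 of 4349 genes with several probe sets and a call (5.82%) had calls in both directions. The count was 7146 with that dose and DMSO alone in the fit and 5401 with array weights, which left replicate 1 of this dose almost out (weight 1.84e-05, against 0.333 and 0.272 for replicates 2 and 3).

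At 100 nM, p53 target genes rose in 21 of 29 and fell in 0 (24 and 0 adjusted over the list alone; median 0.41, adjusted p 2e-40), a call that held with an estimated correlation (adjusted p 2.9e-05). ACER2 rose from 122 ± 1.83 to 288 ± 30.9 (1.13 ± 0.11), TP53I3 by 1.00 ± 0.08, SESN1 by 0.99 ± 0.09 and FAS by 0.73 ± 0.05. CDKN1A rose by 0.43 ± 0.05 and MDM2 by 0.41 ± 0.05, with 7 of the 8 other MDM2 probe sets called up. GDF15 (0.19 ± 0.07, adjusted p 0.16) did not pass the test. Outside that list, UNC5B-AS1, a noncoding RNA, rose by 1.26 ± 0.16, TNFRSF10C, a decoy receptor for the ligand TRAIL, by 1.20 ± 0.17 and the microRNA host MIR34A by 1.20 ± 0.17. MACROD2, an ADP-ribose hydrolase, fell from 97.7 ± 4.75 to 11.9 ± 0.985, a level not shown to be above background (-2.03 ± 0.11 with the offset). FHIT, a gene of a common fragile site, fell from 157 ± 31.8 to 32.2 ± 4.38, also not shown to be above background (-1.83 ± 0.13 with the offset). DHRS2, a short-chain dehydrogenase, fell by 1.54 ± 0.18.

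The other 9 lists called at 100 nM lost the call with an estimated correlation. Nucleotide excision repair rose in 2 of 23 (3 adjusted over the list alone; median 0.06, adjusted p 0.032, and adjusted p = 0.48 with an estimated correlation), namely the damage recognition genes DDB2 (0.70 ± 0.07) and XPC (0.44 ± 0.09), both also in the p53 list. Histone genes H2BC12 (0.51 ± 0.09) and H2BC21 (0.51 ± 0.14) rose, 2 of 7 (2 adjusted over the list alone; median 0.23, adjusted p 0.018, and adjusted p = 0.48 with an estimated correlation). Interferon-stimulated genes rose in 2 of 21, IFIT3 (0.52 ± 0.13) and ISG15 (0.52 ± 0.12; 3 adjusted over the list alone; median 0.15, adjusted p 0.0097, and adjusted p = 0.53 with an estimated correlation). Replication genes fell in 3 of 35, RRM2, a ribonucleotide reductase subunit (-0.19 ± 0.03), MCM10 (-0.25 ± 0.06) and CDC45 (-0.20 ± 0.06; 4 fell and 2 rose adjusted over the list alone; median -0.06, adjusted p 0.033, and adjusted p = 0.53 with an estimated correlation). Of the G2/M list only AURKA was called (-0.14 ± 0.04; 1 of 35, 2 adjusted over the list alone; median -0.07, adjusted p 0.0011, and adjusted p = 0.48 with an estimated correlation). HERPUD1 (-0.33 ± 0.05) and CEBPB (-0.17 ± 0.04) fell, 2 of 26 stress response genes (5 adjusted over the list alone; median -0.06, adjusted p 0.0099, and adjusted p = 0.48 with an estimated correlation). Immediate early genes JUN (-0.57 ± 0.08), KLF6 (-0.44 ± 0.11), IER2 (-0.32 ± 0.08) and JUND (-0.16 ± 0.04) fell, 4 of 23 (6 adjusted over the list alone; median -0.04, adjusted p 0.018, and adjusted p = 0.68 with an estimated correlation). Without 100 nM replicate 1 that list's adjusted p was 0.077, and its median was 0.02 without DMSO replicate 3 and 0.07 without 100 nM replicate 2 (adjusted p 0.61). Hypoxia and glycolysis genes (median 0.07, adjusted p 0.046, and adjusted p = 0.49 with an estimated correlation; 0 of 20 called, 1 adjusted over the list alone) gave 0.34 ± 0.10 for ALDOC and 0.24 ± 0.09 for ENO2. Respiratory chain genes (median 0.07, adjusted p 0.0072, and adjusted p = 0.6 with an estimated correlation; 0 of 27 called, 0 adjusted over the list alone) gave 0.07 ± 0.03 for UQCRB and 0.12 ± 0.04 for NDUFB3. CYP1B1 (0.23 ± 0.11), NQO1 (0.07 ± 0.04) and HMOX1 (0.00 ± 0.14) were not called. The 792 probe sets, 374 up and 418 down, were 442 without DMSO replicate 2 and 3580 with array weights.

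**Figure D4:**
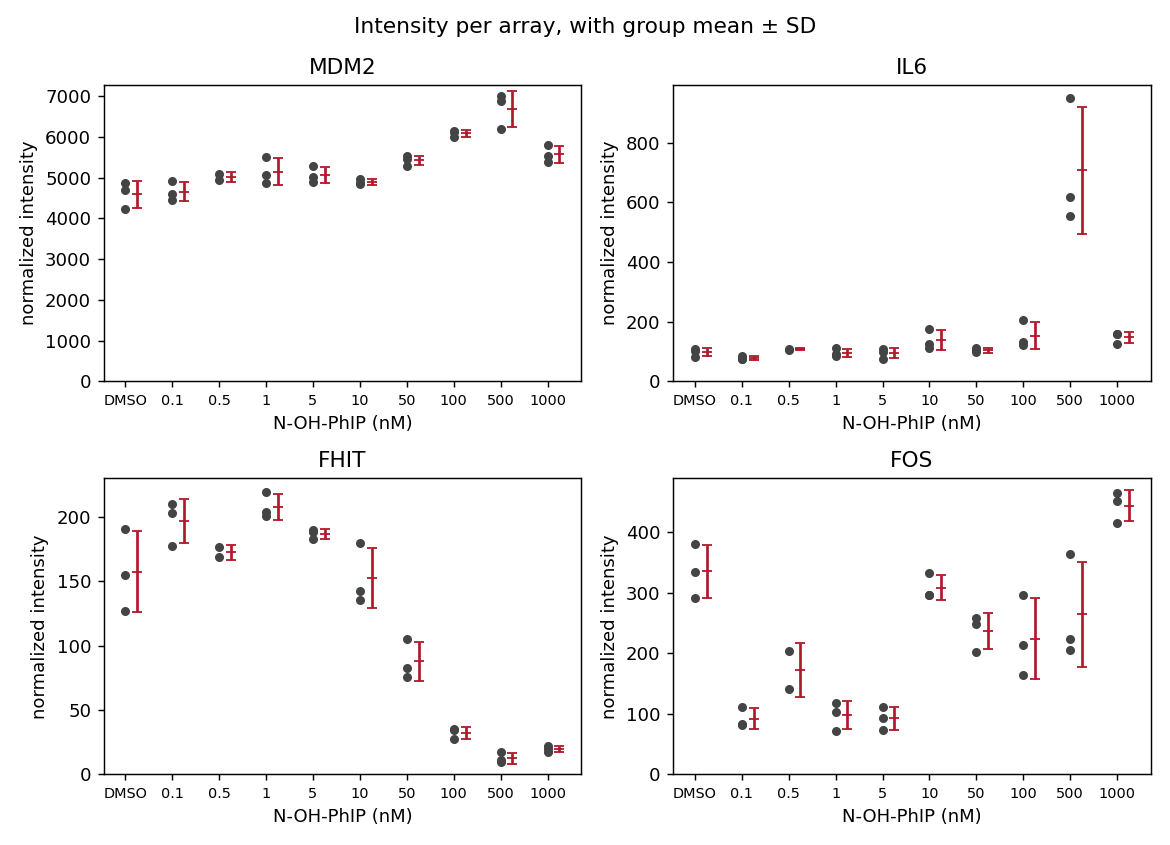
Normalized intensity on each array (points) by dose for MDM2, IL6, FHIT and FOS, with group mean ± SD. FHIT went from 157 in DMSO to 32.2 at 100 nM, a level not shown to be above background. IL6 peaked at 708 at 500 nM, and FOS was 336 in DMSO and 92.4 at 0.1 nM.

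At 50 nM, p53 target genes were the main group to rise, in 11 of 29 with 0 falling (19 and 0 adjusted over the list alone; median 0.25, adjusted p 3.3e-28, and adjusted p 0.00032 with an estimated correlation). ACER2 rose by 0.63 ± 0.11, SESN1 by 0.53 ± 0.09, SPATA18 by 0.43 ± 0.09 and ZMAT3, a zinc finger RNA-binding protein, by 0.42 ± 0.07. CDKN1A rose from 4663 ± 230 to 5527 ± 202 (0.25 ± 0.05, adjusted p 0.042) and MDM2 by 0.24 ± 0.05 (adjusted p 0.041). G2/M and mitosis genes went down as a list, with AURKA called (-0.17 ± 0.04; 1 of 35, 4 adjusted over the list alone; median -0.11, adjusted p 1.8e-14, and adjusted p 0.02 with an estimated correlation). UNC5B-AS1 rose by 0.90 ± 0.16, TNFRSF10C by 0.81 ± 0.15 and MIR34A by 0.78 ± 0.17. DHRS2 (-1.25 ± 0.18), MACROD2 (-1.22 ± 0.11) and HDAC9, a histone deacetylase (-0.79 ± 0.14), fell. GDF15 (0.14 ± 0.07), CYP1B1 (0.05 ± 0.11), NQO1 (-0.03 ± 0.04) and HMOX1 (0.05 ± 0.14) were not called. Immediate early genes were not called as a list (median 0.00, adjusted p 0.1), but were without DMSO replicate 1 (-0.06, adjusted p 0.037) or 50 nM replicate 1 (-0.01, adjusted p 0.0048). Of the 72 probe sets 33 rose and 39 fell. The count was 31 and 8 without DMSO replicates 1 and 2, 28, 14 and 14 without 50 nM replicates 1, 2 and 3, 47 and 41 without 1 nM replicates 1 and 2, and 46 without 0.1 nM replicate 3. It was 43 without the mean-variance trend and 1390 with array weights, and against the 0.1 and 1 nM arrays, a reference chosen after seeing the data, 151.

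At 10 nM, 3 metallothioneins and 3 p53 target genes were higher. MT1G (0.33 ± 0.07), MT1E (0.24 ± 0.05) and MT1F (0.23 ± 0.05), which bind zinc and copper, rose, 3 of 8 (6 adjusted over the list alone; median 0.24, adjusted p 5.5e-08, and adjusted p = 0.051 with an estimated correlation). ZMAT3 (0.38 ± 0.07), TIGAR, a fructose bisphosphatase (0.25 ± 0.05), and FAS (0.24 ± 0.05) rose, 3 of 29 (13 adjusted over the list alone; median 0.15, adjusted p 5e-10, and adjusted p = 0.051 with an estimated correlation). The largest increases were NSD1, a histone methyltransferase (0.84 ± 0.11), PHLDA1 (0.72 ± 0.15) and CUL1, a cullin (0.67 ± 0.14). The mitotic kinesin KIF23 (-0.78 ± 0.16), FANCB (-0.66 ± 0.12) and the linker histone H1-3 (-0.59 ± 0.13) fell. For NSD1, CUL1, KIF23 and FANCB no other tested probe set of the gene passed. For PHLDA1 1 of 5 others passed, but not the brightest, which stands for it in the immediate early list (0.16 ± 0.10). With the brightest probe set of each gene, the other 9 lists called had 0 members past the test over all genes, and limma gave 3649 probe sets at an unadjusted p under 0.05. Their medians were 0.07 for DNA replication and G1/S genes, -0.07 for G2/M, 0.05 for aryl hydrocarbon receptor targets, 0.19 for inflammatory genes, 0.18 for immediate early genes, 0.13 for keratin and adhesion genes, 0.14 for TGF-beta targets, 0.10 for cholesterol synthesis and 0.11 for hypoxia genes. In that order, members up or, for G2/M, down adjusted over the list alone were 5, 1, 2, 7, 2, 7, 2, 0 and 2. With an estimated correlation these lists had adjusted p = 0.42, 0.097, 0.29, 0.31, 0.58, 0.29, 0.34, 0.31 and 0.34. The members with the smallest p gave 0.22 ± 0.06 for MCM7, 0.14 ± 0.04 for RFC5, -0.17 ± 0.04 for HMMR, -0.11 ± 0.04 for AURKA, 0.38 ± 0.11 for CYP1B1 and 0.34 ± 0.11 for IER3. IL1A (0.39 ± 0.11), TNFAIP2 (0.38 ± 0.11), FOSL1 (0.74 ± 0.19), KRT19 (0.35 ± 0.09), CLDN1 (0.20 ± 0.05), ID3 (0.29 ± 0.08) and PMEPA1 (0.24 ± 0.07) did not pass either, nor did MVK (0.27 ± 0.09), NSDHL (0.16 ± 0.06), PDK1 (0.34 ± 0.09) and NDRG1 (0.30 ± 0.09). CDKN1A (0.13 ± 0.05), MDM2 (0.09 ± 0.05), GDF15 (0.23 ± 0.07), NQO1 (0.05 ± 0.04) and HMOX1 (0.14 ± 0.14) were not called.

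Of the 66 probe sets called at 10 nM, 43 rose and 23 fell. The count was 3, 2 and 105 without DMSO replicates 1, 2 and 3, 16 and 1 without 10 nM replicates 1 and 2, 160 and 166 without 500 nM replicates 2 and 3, 100 without 5 nM replicate 1 and 39 without 0.1 nM replicate 3. It was 32 with that dose and DMSO alone in the fit, 28 without the mean-variance trend, 942 with array weights and 1263 (984 up, 279 down) against the 0.1 and 1 nM arrays.

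At 5 nM, where the mean 3′ to 5′ ratio lay above that of DMSO as at 0.1 to 1 nM, immediate early genes were lower. FOS, a subunit of AP-1, fell from 336 ± 44.0 to 92.8 ± 19.3 (-1.70 ± 0.20), EGR3 by 0.98 ± 0.19, SPRY4, a feedback inhibitor of growth factor signalling, by 0.74 ± 0.13 and JUN by 0.73 ± 0.08. In the list 9 of 23 fell and 0 rose (18 and 0 adjusted over the list alone; median -0.46, adjusted p 2.3e-28, and adjusted p = 0.056 with an estimated correlation). EGR1 fell by 1.91 ± 0.25, with 1 of its other 2 tested probe sets called, but not the brightest (-0.22 ± 0.06). The chemokine CXCL8 (-1.19 ± 0.22), TNFAIP3, an inhibitor of NF-kB (-0.89 ± 0.14), and IL1A (-0.49 ± 0.11) fell, 3 of 19 inflammatory genes. CCN2 (-0.95 ± 0.18) and CCN1 (-0.51 ± 0.10), matricellular proteins of both the mesenchymal and the TGF-beta lists, fell, 2 of 15 and 2 of 20. WAC (0.69 ± 0.14), ZNF436-AS1 (0.58 ± 0.14) and LSM8 (0.57 ± 0.13) rose. MT2A (-0.39 ± 0.06), MT1G (-0.29 ± 0.07) and MT1X (-0.24 ± 0.06) fell, 3 of 8 metallothioneins. The mitosis genes CDCA8 (-0.37 ± 0.09), KIF20A (-0.36 ± 0.09) and TPX2 (-0.28 ± 0.07) fell, 3 of 35. ATF3 (-0.47 ± 0.09), HERPUD1 (-0.38 ± 0.05), HSP90B1 (-0.21 ± 0.05) and CEBPB (-0.15 ± 0.04) fell, 4 of 26 stress response genes, as did the heat shock genes DNAJA1 (-0.33 ± 0.05) and HSP90AB1 (-0.29 ± 0.05), 2 of 15. IER3 (-0.46 ± 0.11), TIPARP (-0.39 ± 0.08) and NQO1 (-0.18 ± 0.04) fell, 3 of 9 aryl hydrocarbon receptor targets and, for NQO1, 1 of 23 NRF2 genes. ENO1 (-0.45 ± 0.11) and ADM (-0.39 ± 0.08) fell, 2 of 20 hypoxia genes. The cholesterol genes DHCR7 (-0.36 ± 0.10) and SQLE (-0.26 ± 0.07) and the histone genes H2BC21 (-0.34 ± 0.14) and H2BC5 (-0.28 ± 0.11) did not pass, 0 of 17 and 0 of 7 being called.

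These 13 lists were called at 5 nM, and with an estimated correlation 0 held. Their adjusted p with an estimated correlation were 0.056 for metallothioneins and mesenchymal genes, 0.064 for G2/M, 0.084 for the stress response and cholesterol lists, 0.089 for aryl hydrocarbon receptor targets, 0.099 for NRF2, heat shock, inflammatory and histone genes, and 0.11 for TGF-beta and hypoxia genes. Members down adjusted over the list alone were 5 metallothioneins, 4 mesenchymal, 10 G2/M, 6 stress response, 7 cholesterol, 3 aryl hydrocarbon receptor, 6 NRF2, 4 heat shock, 6 inflammatory, 0 histone, 3 TGF-beta and 6 hypoxia genes, with 1 hypoxia gene up. p53 target genes were not called (median 0.09, adjusted p 0.13), but were without DMSO replicate 3 (0.11, adjusted p 0.028) or 5 nM replicate 1 (0.09, adjusted p 0.049). CDKN1A (-0.05 ± 0.05), MDM2 (0.14 ± 0.05), GDF15 (-0.14 ± 0.07), CYP1B1 (0.04 ± 0.11) and HMOX1 (0.00 ± 0.14) did not pass. Of the 302 probe sets 92 rose and 210 fell. The count was 180, 41 and 195 without DMSO replicates 1, 2 and 3, 755 and 735 without 500 nM replicates 2 and 3, and 124 and 114 without 5 nM replicates 1 and 3. It was 33 with that dose and DMSO alone in the fit, 657 with the 3′ to 5′ ratio as a covariate and 1227 with array weights.

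At 1 nM, immediate early genes fell in 9 of 23 with 0 rising (19 and 0 adjusted over the list alone; median -0.48, adjusted p 9e-34), a call that held with an estimated correlation (adjusted p 0.015). EGR1 fell by 1.87 ± 0.25, FOS by 1.64 ± 0.20, EGR3 by 1.32 ± 0.19, SPRY4 by 0.72 ± 0.13 and JUN by 0.66 ± 0.08. Of the other 2 EGR1 probe sets 1 was called, but not the brightest (-0.21 ± 0.06). TXNIP, an inhibitor of thioredoxin, fell from 2510 ± 146 to 912 ± 339 (-1.52 ± 0.24). Mesenchymal and matrix genes fell in 3 of 15 (4 adjusted over the list alone; median -0.09, adjusted p 3.4e-06, and adjusted p 0.012 with an estimated correlation), namely CCN2 (-1.15 ± 0.18), CDH2, N-cadherin (-0.53 ± 0.11), and CCN1 (-0.48 ± 0.10). Heat shock genes DNAJA1 (-0.32 ± 0.05) and HSP90AB1 (-0.26 ± 0.05) fell, 2 of 15 (5 adjusted over the list alone; median -0.11, adjusted p 3.4e-06, and adjusted p 0.049 with an estimated correlation). CXCL8 (-1.08 ± 0.22) and TNFAIP3 (-0.85 ± 0.14) fell, 2 of 19 inflammatory genes. WAC (0.60 ± 0.14), TRIM22, an interferon-induced ligase (0.55 ± 0.12), and KIAA0232 (0.55 ± 0.10) rose. Of 29 p53 target genes 3 rose and 1 fell (8 and 3 adjusted over the list alone; median 0.09, adjusted p 0.0013, and adjusted p = 0.21 with an estimated correlation), with SPATA18 (0.43 ± 0.09), DDB2 (0.38 ± 0.07) and RPS27L (0.20 ± 0.04) up and PLK2 (-0.56 ± 0.13) down. IER3 (-0.44 ± 0.11), TIPARP (-0.37 ± 0.08), NQO1 (-0.20 ± 0.04), TKT, a transketolase (-0.35 ± 0.07), KRT5 (-0.55 ± 0.13), ADM (-0.36 ± 0.08) and ALDOA (-0.27 ± 0.07) fell.

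The other 8 lists called at 1 nM, all down, lost the call with an estimated correlation, at adjusted p = 0.1 for inflammatory and NRF2 genes, 0.094 for aryl hydrocarbon receptor targets, 0.12 for TGF-beta, cholesterol and hypoxia genes, and 0.37 for keratin and adhesion and G2/M genes. Members called down over all genes were 2 of 19, 2 of 23, 3 of 9, 2 of 20, 0 of 17, 2 of 20, 1 of 30 and 0 of 35, and adjusted over the list alone 6, 4, 3, 2, 3, 4, 2 and 0, with 1 TGF-beta and 2 hypoxia genes up. SQLE (-0.28 ± 0.07), DHCR7 (-0.35 ± 0.10), DLGAP5 (-0.18 ± 0.07) and KIF20A (-0.22 ± 0.09) did not pass, nor did CDKN1A (0.05 ± 0.05), MDM2 (0.16 ± 0.05), GDF15 (0.09 ± 0.07), CYP1B1 (0.26 ± 0.11) and HMOX1 (-0.16 ± 0.14). Of the 213 probe sets 56 rose and 157 fell, against 82 and 122 with arrays centred on their medians. The count was 43 and 137 without DMSO replicates 2 and 3, 336 and 339 without 500 nM replicates 2 and 3, and 50, 107 and 70 without 1 nM replicates 1, 2 and 3. It was 778 with that dose and DMSO alone in the fit, 24 with the 3′ to 5′ ratio as a covariate and 3862 with array weights.

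At 0.5 nM, the dose with 2 arrays, 12 probe sets passed, 3 up and 9 down (8 and 12 with arrays centred on their medians), and limma gave 2919 at an unadjusted p under 0.05. NSD1 (0.69 ± 0.13), PLA2G12A, a phospholipase (0.50 ± 0.08), and CSRNP2 (0.32 ± 0.06) rose. CCN1 (-0.87 ± 0.13), GBP1, a guanylate-binding protein (-0.60 ± 0.10), and JUN (-0.57 ± 0.10) fell. The immediate early list was called down, with another JUN probe set (-0.55 ± 0.08) as 1 of 23 (4 adjusted over the list alone; median -0.09, adjusted p 0.0014, and adjusted p = 0.79 with an estimated correlation), but not without 0.5 nM replicate 3 (-0.02, adjusted p 0.29). p53 target genes (median 0.12; 0 of 29, 4 adjusted over the list alone; adjusted p 3.4e-06, and adjusted p = 0.19 with an estimated correlation) gave 0.24 ± 0.05 for FAS and 0.34 ± 0.08 for ZMAT3. Metallothioneins (median 0.13; 0 of 8, 2 adjusted over the list alone; adjusted p 0.0018, and adjusted p = 0.38 with an estimated correlation) gave 0.25 ± 0.05 for MT1F and 0.15 ± 0.06 for MT1E. Keratin and adhesion genes (median 0.08; 0 of 30, 2 adjusted over the list alone; adjusted p 0.0014, and adjusted p = 0.38 with an estimated correlation) gave 0.41 ± 0.12 for KRT16 and 0.19 ± 0.06 for CLDN1. Mesenchymal genes (median -0.08; 0 of 15, 3 adjusted over the list alone; adjusted p 0.0066, and adjusted p = 0.19 with an estimated correlation) gave, in another CCN1 probe set, -0.53 ± 0.11 for CCN1 and -0.75 ± 0.20 for CCN2. CDKN1A (0.13 ± 0.06), MDM2 (0.13 ± 0.06), GDF15 (0.16 ± 0.08), CYP1B1 (0.32 ± 0.13), NQO1 (0.05 ± 0.05) and HMOX1 (0.12 ± 0.16) were not called. The count was 35, 0 and 2 without DMSO replicates 1, 2 and 3, 63 and 90 without 500 nM replicates 2 and 3, 36 without 100 nM replicate 3, and 0 without either 0.5 nM array. It was 2 with that dose and DMSO alone in the fit, 23 with a replicate block and 685 with array weights.

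At 0.1 nM, FOS fell from 336 ± 44.0 to 92.4 ± 17.1 (-1.70 ± 0.20), EGR1 by 1.68 ± 0.25, EGR3 by 1.38 ± 0.19, JUN by 0.69 ± 0.08 and SPRY4 by 0.66 ± 0.13. EGR3 read 20.5, 31.8 and 32.5 on the arrays of this dose, levels not shown to be above background, so its change depends on the offset. The EGR1 value is from 1 of 3 tested probe sets, of which another was called, while the brightest, which stands for the gene in its list, was not (-0.20 ± 0.06). In the immediate early list 7 of 23 fell and 0 rose (17 and 0 adjusted over the list alone; median -0.44, adjusted p 6.5e-27, and adjusted p = 0.056 with an estimated correlation). CCN2 (-1.08 ± 0.18) and CCN1 (-0.52 ± 0.10) fell, 2 of 15 mesenchymal genes (3 adjusted over the list alone; median -0.10, adjusted p 0.0016, and adjusted p = 0.056 with an estimated correlation) and 2 of 20 TGF-beta targets (2 adjusted over the list alone; median -0.09, adjusted p 0.0034, and adjusted p = 0.22 with an estimated correlation). TNFAIP3 (-0.92 ± 0.14) and IL1A (-0.47 ± 0.11) fell, 2 of 19 inflammatory genes (7 adjusted over the list alone; median -0.27, adjusted p 8.6e-09, and adjusted p = 0.15 with an estimated correlation). The heat shock gene DNAJA1 (-0.31 ± 0.05) fell, 1 of 15 (6 adjusted over the list alone; median -0.12, adjusted p 3.3e-06, and adjusted p = 0.056 with an estimated correlation). HERPUD1 (-0.32 ± 0.05) fell, 1 of 26 stress response genes (2 adjusted over the list alone; median -0.03, adjusted p 0.047, and adjusted p = 0.39 with an estimated correlation). S100A8, a calprotectin subunit (0.95 ± 0.22), ACOT11 (0.73 ± 0.17) and SULF1, a heparan sulfatase (0.72 ± 0.11), rose.

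The other 5 lists called at 0.1 nM had 0 members past the test over all genes, and limma gave 3399 probe sets at an unadjusted p under 0.05. They were p53 target genes (median 0.04), interferon-stimulated genes (0.14), aryl hydrocarbon receptor targets (-0.07), NRF2 genes (-0.05) and cholesterol synthesis genes (-0.06), at adjusted p = 0.39, 0.36, 0.22, 0.36 and 0.29 with an estimated correlation. Adjusted over the list alone, 4 p53 genes were up and 2 down, 1 interferon gene was up, and 3, 2 and 1 genes of the last 3 lists were down. The p53 call was lost without DMSO replicate 2 (adjusted p 0.13). Members with the smallest p gave 0.29 ± 0.07 for ZMAT3, -0.48 ± 0.13 for PLK2, 0.53 ± 0.13 for OASL, 0.36 ± 0.12 for ISG15, -0.37 ± 0.11 for IER3, -0.17 ± 0.04 for NQO1, -0.28 ± 0.07 for TKT, -0.30 ± 0.07 for SQLE and -0.23 ± 0.10 for DHCR7. CDKN1A (-0.01 ± 0.05), MDM2 (0.02 ± 0.05), GDF15 (0.04 ± 0.07), CYP1B1 (0.17 ± 0.11) and HMOX1 (-0.19 ± 0.14) did not pass. Of the 163 probe sets 30 rose and 133 fell, against 44 and 91 with arrays centred on their medians. The count was 717, 29 and 85 without DMSO replicates 1, 2 and 3, 271 and 261 without 500 nM replicates 2 and 3, and 83, 64 and 63 without 0.1 nM replicates 1, 2 and 3. With array weights it was 3159.

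Across the 26 treated arrays, FHIT had a slope of -0.80 ± 0.07 in log2 units per 10-fold dose, LINGO2 -0.75 ± 0.08, MACROD2 -0.71 ± 0.06 and WWOX -0.66 ± 0.07. Of the other 3 tested WWOX probe sets 2 declined and 1 went up. NBEA (-0.74 ± 0.11), LTBP1 (-0.74 ± 0.09), PARD3B (-0.72 ± 0.08), IMMP2L (-0.71 ± 0.10), DIAPH2 (-0.67 ± 0.09) and NALCN, a sodium leak channel (-0.67 ± 0.09), declined as well. The steepest increases were SP6 (0.76 ± 0.11), ID2 (0.76 ± 0.13), LIPG, a lipase (0.72 ± 0.09), NR4A3, an orphan nuclear receptor (0.70 ± 0.08), and SGK1 (0.67 ± 0.11). MARCKSL1 (0.66 ± 0.09), SHISA2 (0.65 ± 0.10), OVOL1 (0.65 ± 0.09), CRISPLD2 (0.64 ± 0.07) and EGR3 (0.65 ± 0.07) followed. Immediate early genes rose with dose in 21 of 23 and p53 target genes in 26 of 29, with 0 falling in either. Further slopes were 0.56 ± 0.06 for ACER2, 0.42 ± 0.06 for TP53I3, 0.42 ± 0.05 for PLK2, 0.38 ± 0.04 for SESN1, 0.58 ± 0.07 for FOSL1, 0.58 ± 0.09 for FOSB and 0.46 ± 0.07 for FOS. CDKN1A (0.18 ± 0.02), MDM2 (0.10 ± 0.02), GDF15 (0.18 ± 0.03), NQO1 (0.13 ± 0.02) and HMOX1 (0.23 ± 0.04) rose with dose, and CYP1B1 fell (-0.15 ± 0.03). These slopes include the low immediate early levels at 0.1 to 5 nM, and the doses of 500 and 1000 nM can carry them. Of the tested probe sets, 2.9% changed against DMSO at 100 nM, 45.4% at 500 nM and 59.9% at 1000 nM. NQO1, HMOX1 and CYP1B1 were not called against DMSO at 100 nM. A slope therefore does not by itself show a graded response over the whole dose range.

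The trend called 12 lists, and with an estimated correlation 0 held, at adjusted p = 0.32 for the p53, immediate early, inflammatory, heat shock, TGF-beta, cholesterol, hypoxia and mesenchymal lists, 0.34 for NRF2, 0.41 for respiratory chain, 0.48 for keratin and adhesion and 0.5 for stress response genes. Called members over all genes in that order were 26, 21, 16, 12, 14, 15, 17, 8, 13, 13, 16 and 1 up, and adjusted over the list alone 27, 22, 16, 12, 14, 15, 17, 8, 13, 13, 16 and 1. Over all genes 1 heat shock, 1 TGF-beta, 1 hypoxia and 1 mesenchymal gene fell, with 4 NRF2, 3 respiratory chain and 5 keratin and adhesion genes (6 adjusted over the list alone). Named members were CXCL8 (0.51 ± 0.10), LIF (0.47 ± 0.05), TNFAIP3 (0.47 ± 0.07), IL6 (0.42 ± 0.10), BAG3 (0.34 ± 0.05), DNAJA1 (0.25 ± 0.03), HSPA4L (0.20 ± 0.03) and DNAJB1 (0.20 ± 0.03). Others were CCN2 (0.51 ± 0.06), BAMBI (0.48 ± 0.10), ANGPTL4 (0.43 ± 0.06), SNAI2, an epithelial-mesenchymal transition factor (0.43 ± 0.06), CCN1 (0.27 ± 0.04) and vimentin, VIM (0.27 ± 0.04). For sterols and glycolysis they were DHCR7 (0.28 ± 0.05), INSIG1 (0.26 ± 0.04), IDI1 (0.25 ± 0.04), SQLE (0.22 ± 0.03), ALDOC (0.50 ± 0.07), ADM (0.45 ± 0.07), PFKFB4 (0.34 ± 0.05) and NDRG1 (0.27 ± 0.06). Keratin and adhesion genes included KRT8 (0.37 ± 0.06), JUP (0.37 ± 0.05), SFN (0.34 ± 0.05) and KRT5 (0.32 ± 0.06). AKR1C3 (0.29 ± 0.04), TKT (0.22 ± 0.03), SRXN1 (0.20 ± 0.04), ATP5F1B (0.15 ± 0.02), NDUFS1 (0.11 ± 0.02), NDUFS3 (0.09 ± 0.01) and NDUFA2 (0.09 ± 0.02) rose. TRIB3 (-0.32 ± 0.05), SLC7A11 (-0.19 ± 0.03) and STC2 (-0.19 ± 0.04) fell, as did 12 of 26 stress response genes, while ATF3 rose (0.20 ± 0.05). With the 3′ to 5′ ratio as a covariate the ATF3 slope was -0.02. In all 16244 probe sets had a trend, 8349 up and 7895 down, against 120 with that covariate, which itself falls at 500 and 1000 nM, and 7698 with array weights.

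The mean of the 9 doses against DMSO, which the 2 highest doses can carry, changed for 22 of 29 p53 target genes, all up (26 adjusted over the list alone; median 0.26, adjusted p 7.7e-26, and adjusted p 0.00056 with an estimated correlation). ACER2 stood at 0.74 ± 0.08, SESN1 at 0.62 ± 0.07, TP53I3 at 0.54 ± 0.06, PHLDA3 at 0.50 ± 0.09, CDKN1A at 0.25 ± 0.04, MDM2 at 0.22 ± 0.04 and GDF15 at 0.26 ± 0.05. The largest other increases were LCE1B (0.92 ± 0.13), UNC5B-AS1 (0.87 ± 0.12), SP6 (0.78 ± 0.08), CEL, a lipase (0.77 ± 0.20), ELAPOR1 (0.76 ± 0.10), DGKE, a diacylglycerol kinase (0.73 ± 0.14), HES2 (0.73 ± 0.10), TNFRSF10C (0.71 ± 0.11) and SRSF11 (0.76 ± 0.15, its other 3 probe sets not called). The largest decreases were LINGO2 (-0.94 ± 0.09), RBMS3 (-0.92 ± 0.12), DPYD (-0.87 ± 0.09), IMMP2L (-0.85 ± 0.09), DHRS2 (-0.83 ± 0.13), PARD3B (-0.83 ± 0.10), MACROD2 (-0.82 ± 0.08), EGR1 (-0.82 ± 0.19, its brightest probe set not called), GLIS3 (-0.81 ± 0.12) and FOS (-0.79 ± 0.15). The other 7 lists called had adjusted p = 0.34 for G2/M, stress response and cholesterol genes, 0.6 for interferon genes, 0.53 for keratin and adhesion, 0.36 for TGF-beta and 0.25 for hypoxia genes with an estimated correlation. Over all genes 5 G2/M and 5 stress response genes fell, and 3 cholesterol, 4 interferon, 7 keratin and adhesion (with 1 down), 6 TGF-beta and 6 hypoxia genes rose. Adjusted over the list alone these were 8 and 5 down, and 9, 5 (with 1 down), 8 (with 1 down), 7 (with 2 down) and 10 up. Named members were AURKA (-0.20 ± 0.03), CDCA3 (-0.25 ± 0.05), BUB1B (-0.19 ± 0.05), HMMR (-0.16 ± 0.03), HERPUD1 (-0.40 ± 0.04), TRIB3 (-0.21 ± 0.05), DNAJB9 (-0.21 ± 0.06) and SLC7A11 (-0.20 ± 0.04). Those that rose were ISG15 (0.56 ± 0.09), OASL (0.41 ± 0.10), IFIT3 (0.38 ± 0.09), TAP1 (0.26 ± 0.07), KRT8 (0.42 ± 0.10), KRT16 (0.36 ± 0.08), CLDN4 (0.29 ± 0.08) and SFN (0.28 ± 0.06). ID2 (0.68 ± 0.09), BAMBI (0.43 ± 0.12), SMAD7 (0.30 ± 0.09), CDKN2B (0.28 ± 0.06), LSS (0.24 ± 0.07), NSDHL (0.18 ± 0.05), HMGCS1 (0.16 ± 0.04), ALDOC (0.41 ± 0.07), ENO2 (0.27 ± 0.07), NDRG1 (0.26 ± 0.07) and ADM (0.22 ± 0.06) rose too. CYP1B1 (0.08 ± 0.09), NQO1 (0.03 ± 0.03) and HMOX1 (0.18 ± 0.10) did not pass. Of 2808 probe sets 1227 rose and 1581 fell, and the count was 1568 and 1151 without DMSO replicates 1 and 2 and 5830 with array weights. A test for any difference among the 10 groups called 18646 probe sets (68.3%). For each of the 104 list values called over the 11 comparisons, median, mean and test had the same sign, and that sign held under each scaling tried.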

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

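Control probe sets of the array, which took no part in the comparisons, differed between groups, and each value below is a log2 change against DMSO with an adjusted p under 0.05 in the limma fit. They were singled out because a signal appeared in data outside the main measurement. At 500 nM, actin 5′ was at 0.563 and actin middle at 0.5016. At 1000 nM, actin 5′ was at 0.6954 and actin middle at 0.5134, and GAPDH 3′ at 0.07581 and GAPDH middle at 0.1168. The 18S ribosomal RNA controls at 1000 nM were at 1.401 (3′), 1.477 (5′) and 0.6342 (middle), and the 28S controls at 1.982 (5′) and 1.275 (middle). The bacterial LysX-M control was at 0.09575, with intensities of 8.06 in DMSO and 9.71 at 1000 nM, near the floor of the table.

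Intensities of 18S went from 215 to 597 (3′), 140 to 420 (5′) and 3241 to 5042 (middle) between DMSO and 1000 nM, and those of 28S from 42.6 to 218 (5′) and 202 to 521 (middle). Actin 5′ stood at 2336 in DMSO, 3491 at 500 nM and 3791 at 1000 nM. Of 62 control probe sets, 1 was called at 0.1 nM and 0 from 0.5 through 100 nM. The 1 at 0.1 nM was 18S middle, which was lower (-0.657), opposite to its direction at 1000 nM. Of 18 hybridisation spike-ins 0 were called at any dose. No explanation of these values was tested.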

How the results depend on the processing

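Of 2722 values of named genes under alternatives, 2510 kept their direction and their side of the threshold, 154 were no longer called, 57 were newly called and 1 reversed. That was ATF3 in the trend, at -0.01726 with the 3′ to 5′ ratio as a covariate. That ratio itself changes at 500 and 1000 nM, so the covariate removes dose effects too. The cause was not tested here or for the counts below, except where fewer probe sets or arrays explain a lower count. Weak signals near background and the offset of 16 limit what can be seen of dim genes.

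With median centring 20 probe sets changed at 0.5 nM. In the upper 25% of mean level, where fewer were tested, the counts were 84 at 0.1, 37 at 0.5, 42 at 50, 456 at 100, 7331 at 500 and 9216 at 1000 nM, 8774 for the trend, 1795 for the mean of doses and 10485 among the 10 groups. Without the mean-variance trend they were 28 at 10 and 43 at 50 nM. Array weights, whose estimates did not converge, gave 3159, 685, 3862, 1227, 942, 1390, 3580 and 5401 from 0.1 through 500 nM, 7698 for the trend and 5830 for the mean of doses. The 3′ to 5′ covariate gave 24 at 1 nM, 657 at 5 nM and 120 for the trend. With only the dose and DMSO in the fit the counts were 2 at 0.5, 778 at 1, 33 at 5, 32 at 10 and 7146 at 500 nM. A minimum of 1.5-fold left 51, 4, 47, 59, 19, 24, 192, 3436 and 6456 from 0.1 through 1000 nM, 5315 for the trend and 114 for the mean of doses. Without both 5 nM replicate 3 and 500 nM replicate 3, 475, 167, 534, 191, 263, 118 and 1276 changed from 0.1 through 100 nM and 4618 in the mean of doses. Against the 0.1 and 1 nM arrays 1263 changed at 10, 151 at 50 and 1846 at 100 nM.

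The replicate block gave 23 probe sets at 0.5 nM in place of 12. Replicate numbers did not pair the arrays in general. Same-numbered arrays of different groups deviated with a median correlation of 0.014, and 37 of 126 pairs lay above 0.1. Of 29 arrays, 9 had a higher mean correlation of deviations with arrays of their own number in other groups than with those of any other number. The highest same-numbered pair reached 0.746, and a batch of the replicate 3 arrays is left undecided below.

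With an estimated correlation the lists called were 0 at 0.1, 0 at 0.5, 3 at 1, 0 at 5, 0 at 10, 1 at 100, 1 at 500 and 3 at 1000 nM, 0 in the trend and 1 in the mean of doses. With fry they were 5, 0, 6, 2, 23 and 25 at 0.1, 0.5, 1, 100, 500 and 1000 nM and 22 in the trend, and with the mean of probe sets 7 at 0.1 nM.

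Leaving out 1 array at a time, counts ran from 29 to 717 at 0.1, 0 to 90 at 0.5, 43 to 339 at 1, 41 to 755 at 5, 1 to 166 at 10, 8 to 98 at 50, 442 to 1037 at 100, 10590 to 13519 at 500 and 14881 to 16955 at 1000 nM. They ran from 14722 to 16350 for the trend, 1151 to 3850 for the mean of doses and 17468 to 20148 among the 10 groups. The 0.5 nM array left alone is then assumed to vary like the other groups. The median of immediate early genes ran from -0.4699 to -0.4006 at 0.1, -0.1686 to -0.01878 at 0.5, -0.5559 to -0.3904 at 1, -0.5732 to -0.3375 at 5, 0.146 to 0.2553 at 10, -0.05728 to 0.03032 at 50, -0.1558 to 0.06722 at 100, 0.2258 to 0.493 at 500 and 0.3126 to 0.4711 at 1000 nM. It turned at 50 nM without DMSO replicate 1 (-0.05728) or 50 nM replicate 1 (-0.0128) and at 100 nM without DMSO replicate 3 (0.0199) or 100 nM replicate 2 (0.06722). That of p53 target genes ran from 0.03026 to 0.07658 at 0.1, 0.1032 to 0.167 at 0.5, 0.07265 to 0.1372 at 1, 0.05381 to 0.1132 at 5, 0.128 to 0.1741 at 10, 0.2324 to 0.3047 at 50, 0.3915 to 0.47 at 100, 0.8338 to 0.9434 at 500 and 0.5964 to 0.6842 at 1000 nM.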

Other observations

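In a comparison of the 2 highest doses chosen after the data were seen, histone and hypoxia genes were higher at 1000 than at 500 nM. All 7 histone genes rose (median log2 1.00, adjusted p = 0.030 with an estimated correlation), with H2BC5 at 1.60 ± 0.11 (SE, 3 arrays per dose) and H2BC12 at 1.49 ± 0.09. Ribosomal RNA controls also stood higher against DMSO at 1000 than at 500 nM (28S 5′ 1.98 and 0.26, 18S 5′ 1.48 and 0.42), and a shared origin in RNA or amplification quality was not tested. Of 20 hypoxia and glycolysis genes 12 rose and 0 fell (median 0.29, adjusted p = 0.030 with an estimated correlation), with NDRG1 at 1.08 ± 0.09 and ALDOC at 1.03 ± 0.10. Of 29 p53 target genes 20 fell and 1, PMAIP1 (0.29 ± 0.08), rose (median -0.29, adjusted p = 0.33 with an estimated correlation), with SPATA18 at -0.94 ± 0.09, TP53I3 at -0.90 ± 0.08 and FAS at -0.68 ± 0.05. IL6 was at -2.11 ± 0.18 and LIF at -0.73 ± 0.12, while BAMBI (2.00 ± 0.16) and ID2 (1.90 ± 0.12) were higher. In all 11820 probe sets differed, 4830 higher and 6990 lower at 1000 nM, and 341 were called in opposite directions against DMSO at the 2 doses.

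Of the 792 probe sets changed at 100 nM against DMSO, 717 also changed at 500 nM against the 0.1 and 1 nM arrays. The group means of these comparisons share no array. The residual variance used at 100 nM came from all 29 arrays, however, those of 500, 0.1 and 1 nM included. In 687 the direction was the same, 331 higher (107 expected for independent lists) and 356 lower (113 expected). Because the lists are not independent, these expected counts are not a chance level, and the overlap is not an independent replication.

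Of the tests that follow, those of RNA degradation and of loss with gene span were chosen only after the result was seen, and what would exclude degradation was narrowed after its value was seen. Long genes were lower at high dose: at 1000 nM, 80.6% of genes in the longest class of span fell, against 19.3% of genes under 10 kb (FHIT spans 1504 kb and ID2 2.41 kb). RNA degradation predicts a higher 3′ to 5′ ratio, while the log2 ratio moved by -0.3343 at 1000 nM, but that of actin went from 2.21 to 1.52 and that of GAPDH from 0.14 to 0.17, so degradation cannot be told apart from an effect of the compound. A normalization error tied to level predicts no difference among genes of like level, but in each of 10 classes of mean level long genes were lower, with -0.5305 the smallest difference, although the last 2 classes held only 17 and 9 long genes. Loss of signal that grows with span may hold, since the difference between 326 genes over 320 kb and 7225 under 40 kb was -0.2984 at 100 nM, -0.84 ± 0.06 (SD) at 500 nM and -1.15 ± 0.05 at 1000 nM (exact p 0.1, the smallest that 3 against 3 arrays allow). The difference was -0.17 ± 0.02 at 50 nM and -0.10 ± 0.02 at 10 nM. At 0.1, 0.5, 1 and 5 nM it was -0.04, -0.07, -0.04 and 0.03. Strict proportion to span was not tested. Whether probes lie in exons was not examined here.

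Of the next tests, those of DMSO standing apart, of an effect from 0.1 through 5 nM and of the 3′ to 5′ ratio were chosen only after the result was seen, and the spread the effect had to pass was set after its value. Immediate early genes were lower at 0.1, 1 and 5 nM, though with an estimated correlation the list's call held only at 1 nM. DMSO arrays standing apart would leave no difference among doses, but the median at 0.1 to 5 nM was -0.3195 against 10 to 100 nM, where 19 of 23 genes were lower (EGR3 by -1.37 ± 0.11 SE, FOS by -1.10 ± 0.11). That comparison called 2843 probe sets, 1811 lower and 1032 higher at 0.1 to 5 nM, so the difference was not confined to this list. Whether these groups of arrays differed in anything besides dose was not tested. EGR3 lay under the level minimum on every array at 0.1 and 1 nM, so the size of its difference depends on the offset. A single deviating array per group is excluded, as the highest list mean at the 3 doses lay below the lowest of DMSO, 10, 50 and 100 nM (-0.03718). An effect holding from 0.1 through 5 nM cannot be told apart from one that is not monotone in dose, as both 0.5 nM arrays lay above those of 0.1 and 1 nM (0.1717) but are only 2 and differed by 0.20. The 3′ to 5′ log2 ratio was higher in mean at these 3 doses (1.23, 1.35 and 1.254, mean 1.279) and at 0.5 nM (1.2504) against 1.165 in DMSO and at 10 to 100 nM. With it as a covariate the list means against DMSO stayed below 0 (-0.46 ± 0.11 SE, -0.3974 ± 0.15 and -0.45 ± 0.12), with upper 95% limits of -0.23, -0.09 and -0.21. The slope on the ratio, estimated within groups only, was imprecise (-0.71 ± 0.55 SE). These limits argue against RNA quality as the whole cause only so far as this ratio reads it. Quality that the ratio does not follow was not tested.

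Of the last tests, those of RNA of the 500 nM culture and of a replicate 3 batch were chosen only after the result was seen, and the bound for calling the batch test undecided was changed after its value was seen. The deviations of 5 nM replicate 3 and 500 nM replicate 3 from their groups correlated at 0.746, and 494 probe sets were 1.5-fold apart in both, 440 of them higher and 0 in opposite directions. RNA of the 500 nM culture in the 5 nM sample predicts a positive slope on the change at 1000 nM. The slope was -0.008915, which argues against it. The change at 500 nM itself was not used, and probe sets were taken as independent, so this does not exclude it. A batch of all replicate 3 arrays cannot be told apart from chance, with a median correlation of 0.07845 for the others (-0.18 to 0.33). Amplification of these 2 samples was taken to predict probe sets of a gene that disagree. They correlated at 0.4535 in the joint deviation, above the bound of 0.370 set beforehand, but at 0.335, below it, in the 5 nM deviation alone. An amplification effect on whole transcripts would leave probe sets of a gene in agreement too, so the test cannot decide. No biological explanation was tested.

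Regroupings of the 6 arrays of a dose and DMSO, set beforehand, give 10 splits, which cannot give a share under 0.05. Each other split mixes arrays of the dose with DMSO, so a true effect widens the spread and lowers its count. The low counts of other splits therefore do not show how many calls chance gives. The grouping of the design was the only 1 of 10 with as many calls at 1000 nM (16345, highest other 0), 500 nM (12392, 2), 100 nM (792, 1), 50 nM (72, 0), 10 nM (66, 0), 5 nM (302, 0) and 1 nM (213, 1). At 0.1 nM 2 of 10 had as many (163, highest other 485), and the other split, DMSO replicate 1 with 0.1 nM replicates 2 and 3, points to a structure of the samples beyond dose. Of 100 splits, 1 had as many calls for the difference among groups (18646, highest other 12078), 1 for the trend (16244, 0) and 2 for the mean of doses (2808, 10359). Which arrays the split with 10359 calls set apart was not examined, so the dose effect itself may carry that count.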
